A study of Mus musculus with 12 samples.

How the data were processed

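The study measured gene expression, hashtag antibodies and T cell receptor (TCR) sequence in single CD8 T cells from mouse spleen, in 2 pools with 2 replicates each. The 12 samples are 4 loadings with 3 kinds of library. Per the file headers the matrices came from Cell Ranger 3.0.1, and per the labels the reads were processed with Cell Ranger and Seurat 3.1 against the mouse build mm9, while the gene annotation is not named in the sources used here. The deposited matrices hold raw UMI counts for 28692 genes and 5 hashtags over all 737280 barcodes, without any filter on cells. The deposited TCR tables list assembled contigs with their UMI counts, chain, V and J genes and CDR3, and they cover 4628, 5440, 5723 and 5489 barcodes in pool 1 replicates 1 and 2 and pool 2 replicates 1 and 2. In this order the hashtag libraries held 27661872, 23784894, 28754752 and 24733795 UMIs, and the depth of the gene libraries opens the results.

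Barcodes with at least 1000 gene UMIs and 500 genes were taken, which gave 4953, 5910, 6114 and 5856. Of these, 4, 2, 2 and 0 with more than 10% mitochondrial UMIs and 4, 8, 15 and 16 with over 2 productive TRB chains were left out. Hashtags were assigned with HTODemux of Seurat 5.3.0 in R 4.3.3 at a positive quantile of 0.99, and 388, 476, 343 and 346 hashtag multiplets were left out as doublets. Doublets within a hashtag cannot be seen this way. Clusters were found with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 0.6), with TCR, immunoglobulin, ribosomal and mitochondrial genes left out. A cluster was named by at least 3 markers of a type among its first 50 genes, unless another type had more markers among its first 10. The rule for removing other cell types, read literally, strikes every cluster with a marker of such a type among its leading genes and would remove 7749 cells, because Klrb1c leads the largest effector-like cluster and Izumo1r is among the leading genes of the exhausted-like cluster. The main analysis asked for 3 markers instead, a choice made after seeing the data, and removed 112 B-cell-like cells, and the literal rule was run as an alternative. In all 21143 cells were kept, 21132 of them with a hashtag.

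For per-cell detection and for the comparisons by Tcf7 and by clone size, each cell was thinned without replacement to 2100 UMIs with seed 1, and 2021 cells below that depth were left out, so 19122 remained. Cells with at least 1 Tcf7 UMI were compared with cells without, and the latter include cells that express Tcf7 below detection. A clone was defined by identical productive TRB V gene, J gene and CDR3 nucleotides within a pool and hashtag, in cells with exactly 1 productive TRB. A clone of at least 5 cells counted as expanded and a clone of 1 cell as single. UMI counts were summed per library, or per library and class with at least 10 cells. Sums were tested with edgeR 4.0.16 (glmQLFit, two-sided glmQLFTest, TMM scaling, filterByExpr), with library as a block for the class comparisons, at a Benjamini-Hochberg adjusted p under 0.05. DESeq2 1.42.0 was the alternative. CPM values are shares of a library's UMIs on the usual scale, without TMM scaling. The median CPM ratio differs from the TMM-scaled one by 0.32 (log2) in the clone comparison, -0.09 in the Tcf7 comparison and -0.03 between pools.

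Gene lists for stem-like and memory, cytotoxic effector, naive-like, inhibitory and exhaustion, tissue residency, proliferation, interferon, immediate early and heat shock, mitochondrial, ribosomal, glycolysis and T cell identity genes, and for B, CD4 T, NK, myeloid, erythroid and sex-linked markers, were fixed together with the tests and most alternatives before the data were examined. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and with an estimated one, and their members were also counted past the threshold over all genes and adjusted over the list alone. With an estimated correlation camera relies on the residual degrees of freedom, which are few in sums per library. A list can then lose its call even where the estimate lies below 0.01. Genes were named by a fixed rule: the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 20 CPM and the same direction in every library, or no overlap between the pools, leaving out TCR and immunoglobulin segments and Tcf7 in its own test. The rule adds up to 4 members per list with the smallest adjusted p and all stem-like and cytotoxic genes, the 5 TRBV genes with the largest mean share and the 3 largest clones per pool. Some genes that the rule names are not reported here. Other list members and other TRBV genes printed with a value were chosen after their values were seen. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and a count of 0 was set against a floor of 3 counts. Single values were compared with exact permutation tests, the spread between clones with 100000 permutations in numpy 2.4.6 and scipy 1.17.1, and TRBV use with Fisher's exact test, by clone size also with an exact conditional test stratified by pool and hashtag.

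The replicates of a pool share most of their cells' clones and hold cells of the same hashtagged samples, so they are repeated loadings, and the p-values measure the spread between these libraries, which may be technical. Replicates still differed by more than sampling noise, with a chi-square per degree of freedom of 5.26 in pool 1 and 3.40 in pool 2, against 6.96 to 15.8 between libraries of different pools. The hashtags and pools carry no stated treatment, so hashtags were not grouped by their values, and the results give their values as median and range. Single values per hashtag are among the other observations. Flagged results include fits of class and pool in sums per hashtag, in which the hashtags of a pool served as its replicates. Near-identical genes, such as Ifit3 and Ifit3b, Hspa1a and Hspa1b, the Klra family and ribosomal proteins with pseudogenes, can exchange reads, and their single values are uncertain. The edgeR fits were tested on simulated data with 100 genes changed at each of 2 sizes: at a log2 difference of 1 they recovered 100% (pools), 100% (Tcf7) and 96% (clones), at 0.5 they recovered 83%, 87% and 46%, and 3.17%, 5.08% and 6.58% of calls were false. The changed genes were drawn from those with higher counts, and all genes shared 1 dispersion, taken from the real sums. Far fewer genes were changed than the class comparisons called. These rates therefore do not cover genes with low counts or the spread between samples. Alternatives covered the tool, scaling, filters, depth, class and clone definitions, the unit of summing, and each library left out in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.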

Results

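C57BL/6 mice, an inbred laboratory strain, were vaccinated with 2 doses given 2 weeks apart of a synthetic nanoparticle vaccine that carries peptide antigen and a TLR-7/8 agonist, a compound that stimulates innate receptors for single-stranded RNA. Antigen-specific CD8 T cells were sorted from the spleen 2 weeks later and loaded as 2 pools with 2 replicates each, named pool 1 and pool 2. Each of the 4 loadings gave 3 droplet libraries, for gene expression, for hashtag antibodies that mark the sample a cell came from, and for T cell receptor (TCR) sequence, which makes 12 samples. The labels do not say what differs between the pools or what the 5 hashtags mark.

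The gene expression libraries held 18797491 and 21637254 unique molecular identifiers (UMIs) in pool 1 and 23596895 and 23487063 in pool 2. After filtering, 4533, 5393, 5741 and 5476 cells were kept, with medians of 3179, 3108, 3320 and 3395.5 UMIs and 1392, 1377, 1406 and 1436 genes per cell. Exactly 1 productive TCR beta chain (TRB) was read in 85.2%, 83.5%, 82.8% and 82.6% of the kept cells. Genes were compared as sums of UMIs per library, and only Tcf7 detection was read per cell, at equal depth.

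Clustering gave 6 kinds of cells with a name from markers fixed beforehand, and cells left unnamed. The larger effector-like cluster was led by Gzma, a serine protease of cytotoxic granules, and had Klrg1, Zeb2 and the NK receptor gene Klrb1c among its leading genes. The smaller one, of 1773 cells, was led by Nr4a1, Ccl3 and Rhob. It was named by Zeb2, S1pr5 and Cx3cr1, the minimum of 3 markers. The larger stem-like cluster, of 4065 cells, was led by Xcl1, a chemokine for cross-presenting dendritic cells, Car2 and Socs3. The naive marker Dapl1, the inhibitory receptor gene Ctla4 and Id3 were among its first 10 genes. The smaller stem-like cluster, of 142 cells, was led by Id3, Car2 and Nsg2, with Dapl1 and Slamf6 among its first 10. A naive-like cluster had Igfbp4 and Ccr7 among its leading genes. Small clusters were interferon-responding-like (Ifit1, Ifit3, Isg15), exhausted-like (Lag3, Ctla4, Tox, with Hic1 and Asb2 in front) and proliferating-like (Birc5, Mki67). The largest unnamed cluster was led by Tigit, Swap70 and Itgax, and the other one by Klf2 and Gm42418 at a median of 1319.5 UMIs per cell.

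The effector-like share of kept cells was 48.9% (exact 95% interval 47.4 to 50.4) and 48.3% (47.0 to 49.6) in the replicates of pool 1 and 39.7% (38.4 to 41.0) and 39.6% (38.3 to 40.9) in those of pool 2. The stem-like share was 15.1% (14.1 to 16.2), 14.9% (14.0 to 15.9), 24.7% (23.59 to 25.8) and 23.7% (22.6 to 24.9) in the same order. Naive-like cells made up 4.90% (4.29 to 5.57), 4.54% (4.003 to 5.13), 6.62% (5.99 to 7.29) and 7.58% (6.89 to 8.31). The exhausted-like cluster held 6, 16, 57 and 59 cells and the proliferating-like cluster 11, 32, 17 and 15. Because genes that define these clusters differed between the pools, the sizes are given per library and were not compared between pools. At a Leiden resolution of 0.4 no cluster was named stem-like: a cluster of 4834 cells had 5 stem-like markers among its first 50 genes, but its first 10 held 2 exhaustion markers, Ctla4 and Tox, and 1 stem-like marker, Xcl1.

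**Figure D1:**
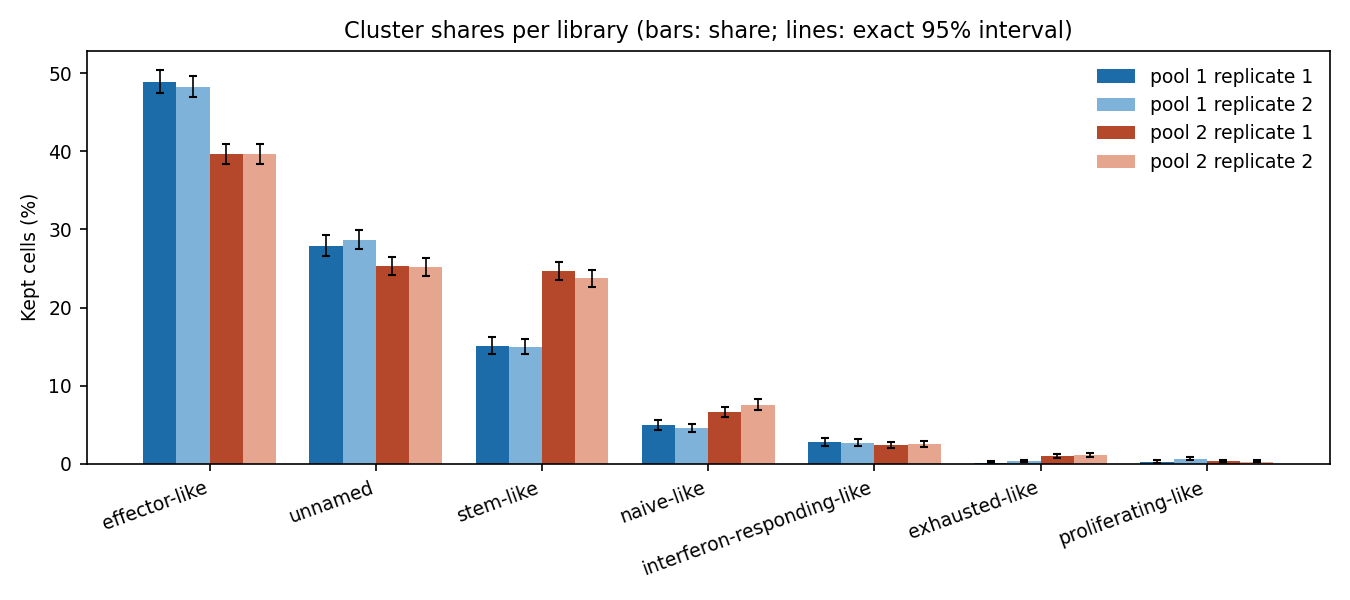
The percentage of kept cells (y axis) in each named kind of cluster (x axis) is drawn as bars for the 4 libraries, with exact 95% binomial intervals. Effector-like cells range from 39.6% to 48.9% and stem-like cells from 14.9% to 24.7% across the libraries.

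The series title concerns stem-like cells with TCF1, the transcription factor encoded by Tcf7 (ENSMUSG00000000782), and the share of cells with a Tcf7 UMI was therefore measured first. With every cell thinned to 2100 UMIs, Tcf7 was detected in 19.95% (18.7 to 21.2) and 19.3% (18.2 to 20.5) of cells in pool 1 and in 22.1% (21.0 to 23.2) and 22.2% (21.0 to 23.3) in pool 2. Naive-like cells carried a Tcf7 UMI in 46.6% (43.7 to 49.5) of cases, stem-like cells in 40.5% (38.9 to 41.99), and effector-like cells in 8.99% (8.39 to 9.61). Tcf7 was in 22.0% (18.5 to 25.9) of interferon-responding-like and in 6.15% (2.69 to 11.8) of exhausted-like cells. Tcf7 belongs to the markers that name the stem-like clusters, so these shares describe the clusters. B-cell-like cells, which should lack Tcf7, showed it in 3 of 63 cells, or 4.76% (0.993 to 13.3), at a median of 3233 UMIs. That cluster is not a clean background, as 11.6% of its cells had a productive TRB and Cst3 and Tyrobp were among its leading genes. The share in effector-like cells, whose median was 2960 UMIs, lay within that wide interval, as did those of exhausted-like and proliferating-like cells. An interval from 3 cells cannot tell whether these shares are background. In droplets with 10 to 100 UMIs, Tcf7 stood at 132 to 171 CPM, against 127 to 154 CPM in kept cells. Per droplet this was little: 46, 57, 39 and 64 Tcf7 UMIs in 16219, 16119, 16076 and 18436 such droplets of the 4 libraries. If droplets with cells took up a similar amount, these values argue against free transcript as the main source of the 8.99% in effector-like cells. They do not bear on doublets.

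The mean share was 19.6% ± 0.438 (SD, n = 2 libraries) in pool 1 and 22.1% ± 0.0604 (SD, n = 2) in pool 2, a difference of 2.48 percentage points. The exact two-sided permutation test of 2 against 2 libraries gave p = 0.333, the smallest it can give, so this test cannot show a difference for a single value, whatever its size. Without thinning, the shares were 28.8%, 27.1%, 32.7% and 33.4%.

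**Figure D2:**
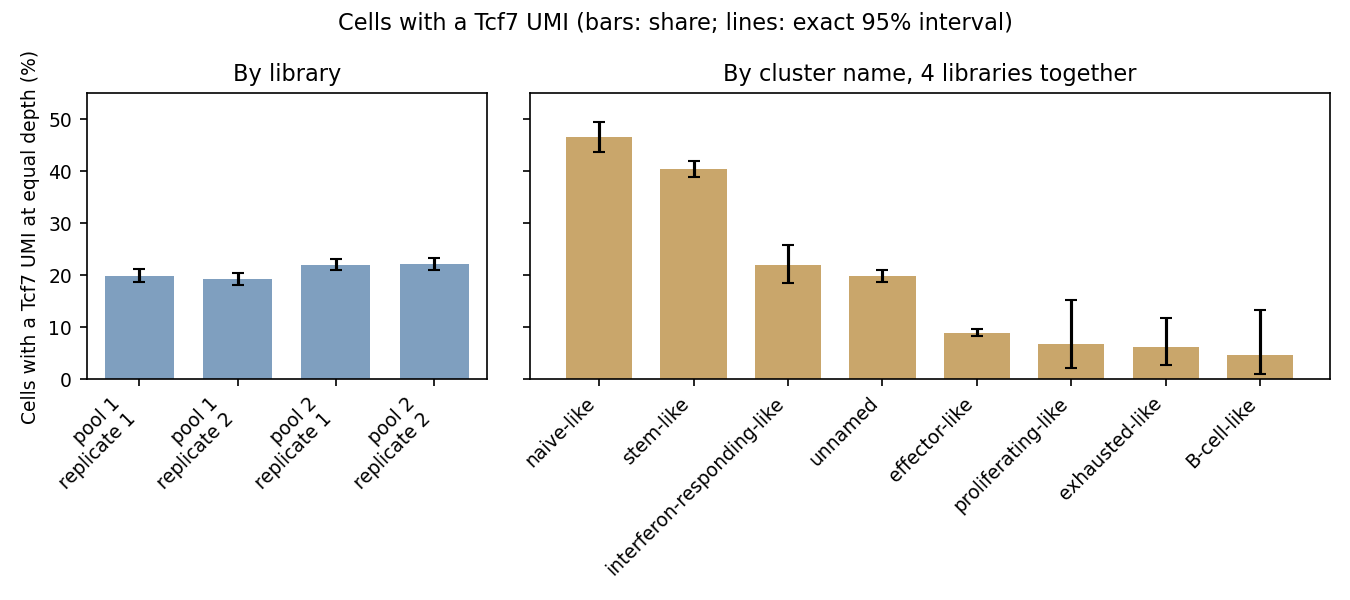
The percentage of cells with at least 1 Tcf7 UMI at 2100 UMIs per cell (y axis) is shown for the 4 libraries on the left and by cluster name, over the 4 libraries together, on the right, with exact 95% binomial intervals. Libraries lie between 19.3% and 22.2%, whereas clusters run from 4.76% in B-cell-like cells to 46.6% in naive-like cells.

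Cells with a Tcf7 UMI were next compared with cells without one inside each library. Cells with Tcf7 held more transcript of stem-like and naive-like genes and less of cytotoxic effector genes, although the cytotoxic list did not hold in camera with an estimated correlation. Ccr7 (ENSMUSG00000037944), the chemokine receptor for entry into lymph nodes, rose by 1.90 ± 0.06 on the log2 scale (SE, n = 4 libraries), from 57.4 ± 11.5 to 202 ± 12.5 CPM (SD). Gzma (ENSMUSG00000023132) fell by 1.83 ± 0.04 on the log2 scale, from 3732 ± 618 to 1004 ± 319 CPM. After Ccr7, the largest rises among genes of at least 20 CPM included those of Nsg2 (1.80 ± 0.07), Id3 (1.73 ± 0.10), a regulator of memory T cell formation, and Fam101b (1.67 ± 0.09). Dapl1, Rgs10, Car2, Cd9 and Actn1 followed, with rises between 1.23 and 1.59. After Gzma, the largest falls were those of the potassium channel gene Kcnj8 (-1.49 ± 0.08), of Gzmb (-1.40 ± 0.05), of Klrg1 (-1.31 ± 0.05), a marker of terminal effector cells, and of Esm1 (-1.30 ± 0.11). Il12rb2, a chain of the interleukin-12 receptor, S1pr5, Zeb2, Cx3cr1 and Tktl1 fell by 1.27 to 1.19. Library sums mix hashtags with different Tcf7 shares, and in sums per pool and hashtag the differences were smaller: Ccr7 1.16 ± 0.07, Nsg2 1.08, Id3 1.09, Fam101b 1.01, Dapl1 0.88 and Car2 0.66, and Gzma -1.66 ± 0.12, Kcnj8 -1.10, Gzmb -1.19, Klrg1 -0.83 and Esm1 -0.81.

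Of the 17 measured genes of the stem-like and memory list other than Tcf7, 14 rose, none fell and 3 did not pass, and adjusted over the list alone 15 rose and 1 fell. Without the naive-like and proliferating-like clusters, a choice made after seeing the data, 11 rose and Klf2 (-0.11) fell, and Lef1 (0.09), Satb1 (-0.12) and Bach2 (0.37) did not pass. Slamf6, a surface receptor used to mark stem-like cells, rose by 1.13 ± 0.07, Xcl1 by 1.06 ± 0.08, and the rare transcripts of Myb and Cxcr5 by 2.27 ± 0.27 and 1.48 ± 0.29. In sums per pool and hashtag Slamf6 stood at 0.75 ± 0.07 and Xcl1 at 0.34 ± 0.08, higher in 8 of 10 and lower in 2. The members that did not pass were Klf2 (-0.05 ± 0.02), Eomes (0.22 ± 0.09) and S1pr1 (-0.04 ± 0.04). Of the 23 cytotoxic effector genes, 22 fell and none rose, with the same count adjusted over the list alone. Ifng, the interferon gamma gene, was the member that did not pass, at -0.04 ± 0.03. Without the naive-like and proliferating-like clusters Ifng passed as a rise, at 0.087. The chemokine gene Ccl5 took the most UMIs of the list and fell from 35683 ± 1528 to 23202 ± 2576 CPM (SD, n = 4). Of the 10 naive-like genes, 9 rose and Npm3 fell, also adjusted over the list alone, and some of them, such as Ccr7 and Lef1, are also on the stem-like list.

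Inhibitory and exhaustion genes divided, with 7 of 13 higher and 2 lower in cells with Tcf7, also adjusted over the list alone. Cd200 (1.39), Rgs16 (1.04), the exhaustion-associated transcription factor gene Tox (0.83) and Ctla4 (0.80) rose, whereas Entpd1 (-0.97) and Havcr2 (-0.85) fell. All 16 measured ribosomal protein and translation genes rose, with a median of 0.44 and Rpl13 at 0.49 ± 0.01, and so did all 13 mitochondrially encoded transcripts, with a median of 0.19 and mt-Co1 at 0.19 ± 0.01. Both counts were the same adjusted over the list alone, and every member was also higher by CPM without TMM scaling. Reads of ribosomal protein genes can also match their pseudogene copies, so single values of that list are uncertain. Among immediate early and heat shock genes 7 of 15 rose and 4 fell, or 8 and 4 adjusted over the list alone; Jun (0.57) and Fos (0.33) rose, and Hspa1a and Hspa1b, which share nearly all their sequence, fell by 0.67 and 0.45. In the interferon list 6 of 16 rose and 2 fell, or 7 and 2 adjusted over the list alone, with Ifi27l2a at 0.57 and Mx1 at -0.52. Proliferation genes had 1 rise and 4 falls among 12, or 1 and 5 adjusted over the list alone, and Stmn1 fell by 1.03.

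Tissue residency genes had 2 rises, Cd69 (0.49) and Itgae (1.37), and 2 falls, Cxcr6 (-0.73) and Itga1 (-0.66), among 6 measured, also adjusted over the list alone. Among 13 glycolysis genes, 2 rose (Gpi1 and Gapdh) and 1 fell (Slc2a3), or 3 and 2 adjusted over the list alone. T cell identity genes had 2 rises, Cd3d (0.26) and Cd8a (0.17), and 5 falls among 9, led by Cd2 (-0.21), also adjusted over the list alone. Markers of other cells moved as well. Of 4 B cell genes Ighm (1.49) and Cd79b (0.79) rose and Igkc (-0.66) fell. Of 3 CD4 T cell genes Izumo1r (1.69) rose and Il2ra (-0.85) fell. Of 3 NK and innate lymphoid genes Klrb1c (-1.09) and Fcer1g (-1.11) fell, and adjusted over the list alone all 3 fell, while the B cell and CD4 T cell counts stayed as they were. Neither of 2 myeloid genes passed, none of the erythroid genes was measured in any of the 3 comparisons, and Xist, the single measured sex-linked gene, rose by 0.14.

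In all, 1663 of 9538 genes passed in the edgeR quasi-likelihood test with library as a block, 887 higher and 776 lower. In limma's camera the adjusted p was 6.41e-12 for the stem-like, 4.12e-20 for the cytotoxic, 4.12e-11 for the naive-like, 0.00297 for the inhibitory, 5.89e-15 for the ribosomal, 1.97e-06 for the mitochondrial, 0.00734 for the proliferation and 0.0329 for the NK list. The stem-like and naive-like lists held with an estimated correlation, at an adjusted p of 0.0431 each, but at 0.0697 each without the naive-like and proliferating-like clusters, a choice made after seeing the data, and at 0.00167 (stem-like) and 0.00306 (naive-like) in sums per pool and hashtag. The others did not, with an adjusted p = 0.175 (cytotoxic), 0.124 (inhibitory), 0.114 (ribosomal), 0.105 (mitochondrial), 0.282 (proliferation) and 0.397 (NK) with an estimated correlation. That estimate was -0.0194 for the inhibitory list, below the preset 0.01, and 0.0329 (mitochondrial) to 0.833 (NK) for the rest of these. Few residual degrees of freedom also weaken this test. For the interferon list the adjusted p was 0.0514, for the immediate early list 0.131, and between 0.332 and 0.994 for the other lists tested. DESeq2 called 711 genes, a fit without the library block 1101, unthinned cells 3882, and cells with at least 2 Tcf7 UMIs 3852. In sums per pool and hashtag 590 genes passed, of which 585 were among those of the main test and all 585 kept their direction, and the stem-like list then had 10 rises among 15 and the cytotoxic list 21 falls among 22. Other lists lost calls in these sums: inhibitory genes had 2 rises and 1 fall among 11, with a camera adjusted p of 0.461, interferon genes 1 rise and no fall among 15, mitochondrial transcripts 11 rises among 13, and proliferation genes 1 rise and 1 fall among 8, with a camera adjusted p of 0.109. Immediate early and heat shock genes had 4 rises and 2 falls among 15, T cell identity genes 1 and 1 among 9, and glycolysis genes 1 and 0 among 12. Without the naive-like and proliferating-like clusters proliferation genes had 1 rise and 1 fall among 11, with a camera adjusted p of 0.417. In sums per pool and hashtag the median of the ribosomal list was 0.25 with 16 of 16 higher, Tox stood at 0.24 with an edgeR adjusted p of 0.0838, and Igkc (-0.07), Cd79b (0.32) and Il2ra (-0.45) did not pass.

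Clones were defined by TRB sequence within a pool and hashtag, to ask how receptor-sharing families of cells relate to these states. The replicates of pool 1 shared 127 TRB nucleotide sequences, 33.7% (28.9 to 38.7) of those of the first replicate, and these covered 93.3% of its cells. The replicates of pool 2 shared 154, or 26.2% (22.7 to 29.99), covering 90.4% of cells. Between libraries of different pools 6 to 8 sequences were shared, covering 9.32% to 9.69% of cells. Of the sequences shared within a pool, 125 of 127 and 153 of 154 carried the same hashtag in both replicates, so the replicates hold cells of the same hashtagged samples. Over both pools 1680 clones were found in 17639 cells, 669 in pool 1 and 1011 in pool 2. The 209 clones of at least 5 cells held 90.5% of these cells, and 1355 clones were seen in a single cell.

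Naive-like cells were nearly all unique by receptor, since 1115 of 1135 (98.2%, 97.3 to 98.9) belonged to single-cell clones. They made up 82.3% of all cells of single-cell clones, against at most 0.0710% of the cells of expanded clones in any library. Stem-like cells were single in 3.56% (2.998 to 4.196) of cases and effector-like cells in 0.478% (0.335 to 0.662). Clones of 100 or more cells held 2225 of 3847 stem-like cells and 6228 of 7525 effector-like cells.

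**Figure D3:**
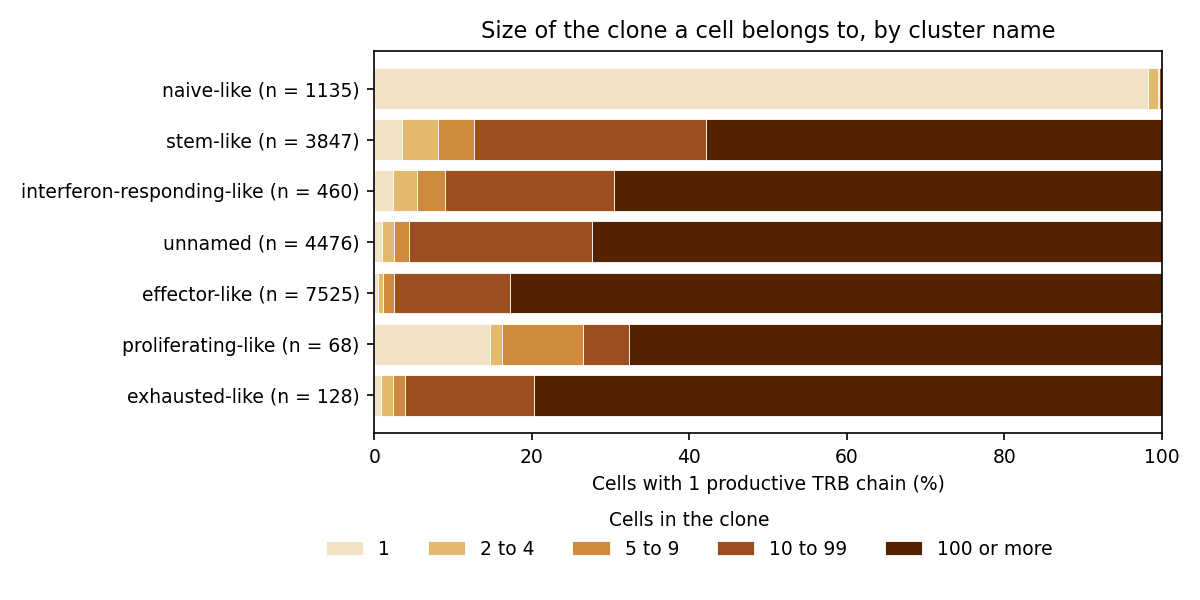
Stacked bars give the percentage of cells (x axis) by the size of the clone they belong to, for each cluster name (y axis), over the 4 libraries. Naive-like cells are almost all in single-cell clones (98.2%), compared with 3.56% of stem-like and 0.478% of effector-like cells.

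Cells of expanded clones were compared with cells of single-cell clones inside each library. Expanded clones held more transcript of cytotoxic and terminal effector genes, and single-cell clones more of naive-like genes, although in sums per library neither list held in camera with an estimated correlation. Gzma rose by 3.58 ± 0.07 on the log2 scale (SE, n = 4 libraries), from 243 ± 155 CPM (SD) in single-cell clones to 3311 ± 589 in expanded clones. Ccr7 fell by 4.24 ± 0.06, from 665 ± 31.8 to 43.1 ± 9.15 CPM. The largest rises rest on few UMIs in single-cell clones, 4 for Car5b (4.48 ± 0.38; 29.3-fold, with a counting interval of 11.4 to 108), a mitochondrial carbonic anhydrase gene, and 6 each for Esm1 (3.92 ± 0.35) and Fcgr2b (3.84 ± 0.35), an inhibitory Fc receptor gene, so their order is uncertain. With them were Zeb2 (3.85 ± 0.16), a transcription factor gene of terminal effector cells, and Klrg1 (3.71 ± 0.15). Cx3cr1, Osbpl3, S1pr5 and the chemokine receptor gene Ccr2 rose by 3.50 to 3.69. Naive-like cells are most of the single-cell class, and without the naive-like and proliferating-like clusters, a choice made after seeing the data, the differences were Gzma 1.47 ± 0.07, Zeb2 1.70, Klrg1 1.46, Cx3cr1 1.44, Car5b 2.23 and Ccr7 -1.73. In sums per pool and hashtag Gzma rose by 2.57 ± 0.12 and Ccr7 stood at -3.29. The deepest falls were near the limit of counting. Igfbp4 had 421 UMIs in single-cell clones and 1 in expanded clones, a 4812-fold lower level with a counting interval of 859 to 190498, and the gut homing receptor gene Ccr9 had 149 and 1, a 1703-fold lower level (301 to 67709). Tmem108 (-8.87 ± 0.31), Ramp1 (-6.91 ± 0.25), Atp1b1 (-5.26 ± 0.26), Itgae (-4.92 ± 0.27) and Treml2 (-4.68 ± 0.23) came next, and Tdrp and Ppic fell by 4.50 and 4.28.

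All log2 values here are relative to TMM scaling, and CPM without it shifts the median of all genes by 0.32 upwards in expanded clones. Of the 18 stem-like genes 14 fell and 2 rose, also adjusted over the list alone. Lef1 fell by 2.66 ± 0.06, Id3 by 2.23 ± 0.14 and Tcf7 itself by 1.61 ± 0.07, whereas the chemokine receptor gene Cxcr3 rose by 1.42 ± 0.11 and Il7r by 0.31 ± 0.05, and by CPM without TMM scaling Klf2 and S1pr1 went the other way. Eomes (-0.03 ± 0.16) and Xcl1 (-0.02 ± 0.14) did not pass, but Xcl1 passed in opposite directions in other settings, at 0.97 ± 0.15 in sums per pool and hashtag and at -1.56 ± 0.21 without the naive-like and proliferating-like clusters. Of the 23 cytotoxic genes 22 rose and none fell, also adjusted over the list alone, with a median of 2.64 and Gzmb at 3.02 ± 0.09. Klra9 had 3 UMIs in single-cell clones and 100 in expanded clones, a ratio of 2.92 (0.970 to 14.4), and did not pass. Of the 10 naive-like genes 9 fell and none rose, with a median of -3.13. Inhibitory genes had 7 rises and 1 fall among 13, and Entpd1 (2.61), Pdcd1 (2.33), which encodes PD-1, and Lag3 (2.01) rose, whereas Tnfrsf9 (-2.36) fell. Havcr2 had no UMI in single-cell clones and 543 in expanded clones, a level at least 15.8-fold higher against a floor of 3 counts over the group. All 16 ribosomal and translation genes fell, with a median of -1.11, and all 13 mitochondrial transcripts fell, with a median of -0.61, and both lists were also lower by CPM without TMM scaling. The counts of the naive-like, inhibitory, ribosomal and mitochondrial lists were the same adjusted over the list alone. Without the naive-like and proliferating-like clusters, 16 of 16 ribosomal and translation genes fell, with a median of -0.39. Only 3 of 13 mitochondrial transcripts fell in that setting, with a median of -0.097.

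Immediate early and heat shock genes had 6 rises and 6 falls among 15, with Jun at -1.16 and Hspa1a at 2.02, and by CPM without TMM scaling Junb, Hspa8 and Dusp1 went the other way. In the interferon list 5 of 16 rose and 2 fell, with Mx1 at 1.30, and the fall of Bst2 (-0.29) went the other way by CPM. Proliferation genes had 4 rises and 2 falls among 12, with Cdk1 at 1.90 and Tubb5 at -0.90. Tissue residency genes had 3 rises and 2 falls among 6, with Cxcr6 at 2.24 and Cd69 at -0.93. Glycolysis genes had 2 rises and 2 falls among 13, or 2 and 3 adjusted over the list alone, and the fall of Gpi1 (-0.32) went the other way by CPM. T cell identity genes had 4 rises and 2 falls among 9, with Thy1 at 0.58 and Cd8a at -0.74. Among markers of other cells, Cd79b (-1.58) fell of 2 B cell genes, Il2ra (2.32) rose and Izumo1r (-1.88) fell of 3 CD4 T cell genes, Klrb1c (2.94) rose and Fcer1g (-1.86) fell of 3 NK genes, and both myeloid genes, Cst3 (0.33) and Cd68 (1.54), rose. Xist fell by 0.17 and went the other way by CPM. Adjusted over the list alone, the counts of these lists were the same except for glycolysis. Fewer calls were left without the naive-like and proliferating-like clusters, where only 214 cells of single-cell clones remained at equal depth. Immediate early and heat shock genes then had 1 rise and 1 fall among 15, and interferon genes 0 rises and 1 fall among 16. Proliferation genes had 1 rise and 0 falls among 11, and tissue residency genes 1 rise and 1 fall among 5.

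In all, 2921 of 9270 genes passed in edgeR, 1411 higher and 1510 lower in expanded clones. In limma's camera the adjusted p was 3e-07 for the stem-like, 2.91e-16 for the cytotoxic, 7.25e-11 for the naive-like, 0.0334 for the inhibitory, 4.05e-14 for the ribosomal and 1.6e-08 for the mitochondrial list, and between 0.574 and 0.973 for the others tested. None held with an estimated correlation in sums per library, at an adjusted p = 0.164 for the stem-like, cytotoxic and naive-like lists, 0.238 for the inhibitory and mitochondrial lists and 0.2496 for the ribosomal list. The estimates ran from -0.0243 (inhibitory) to 0.837 (ribosomal), and this test has few residual degrees of freedom. In sums per pool and hashtag, however, the adjusted p with an estimated correlation was 0.000218 for the stem-like and naive-like, 0.0227 for the cytotoxic and 0.0139 for the inhibitory and ribosomal lists, and without the naive-like and proliferating-like clusters it was 0.0295 for the stem-like, naive-like and ribosomal lists. In sums per pool and hashtag 1722 genes passed, 1668 of them among those of the main test and all 1668 in the same direction, with 22 of 22 cytotoxic genes higher, 9 of 16 stem-like genes lower and 3 (Cxcr3, Xcl1 and Il7r) higher, and Slamf6 (-0.53 ± 0.12 in the main test) at 0.15. Without the naive-like and proliferating-like clusters, a choice made after seeing the data, 279 genes passed, and 20 of 23 cytotoxic genes rose, 7 of 18 stem-like genes fell and 2 (Klf2 at 0.30 and S1pr1 at 0.57) rose, 5 of 9 naive-like genes fell, inhibitory genes had 1 rise and 2 falls among 13 with a median of -0.27 (Lag3 at 0.0017, Entpd1 and Pdcd1 not past the threshold), Il7r turned to -0.04, Cxcr3 (0.04) and Lef1 (-0.58) no longer passed, and Tcf7 stood at -0.45 with an adjusted p of 0.239 in edgeR. That setting left 214 single cells. Random draws of as many from all single-cell clones called 816 to 934 genes, so lost calls partly reflect fewer cells.

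**Figure D4:**
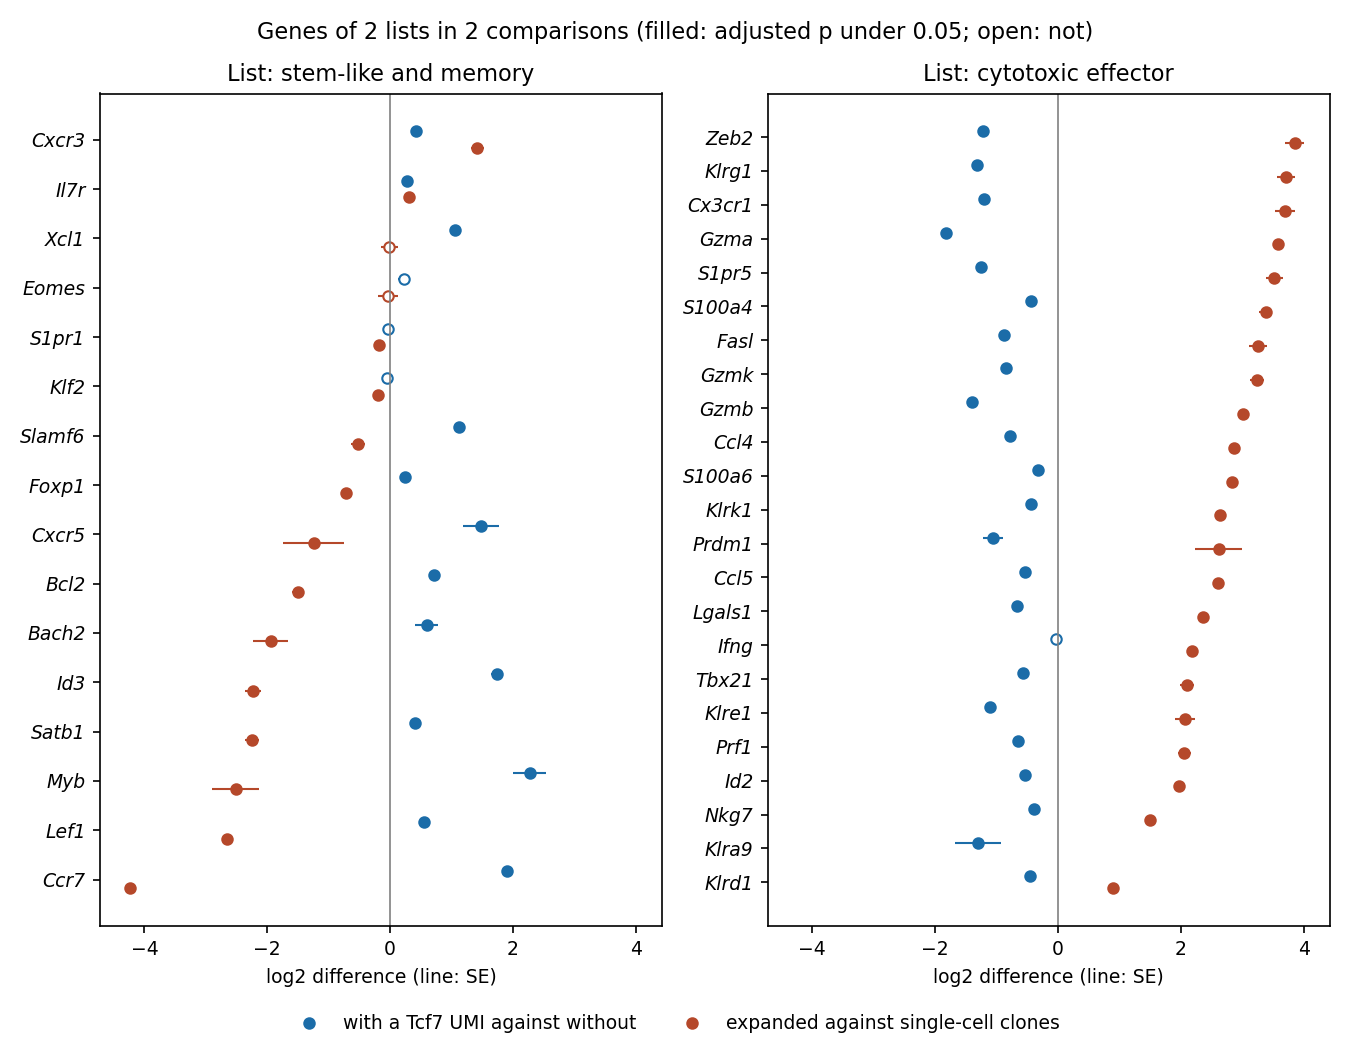
Points give the log2 difference with its SE (x axis) of stem-like and cytotoxic genes (y axis) between cells with and without a Tcf7 UMI and between expanded and single-cell clones, filled where the edgeR adjusted p was under 0.05. Cytotoxic genes lie at negative values with Tcf7 (Gzma at -1.83) and at positive values in expanded clones (Gzma at 3.58), stem-like genes mostly the other way, and by CPM without TMM scaling Klf2 and S1pr1 change sign in the clone comparison.

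Tcf7 detection was lower in expanded than in single-cell clones in 4 of 4 libraries. The mean share was 19.6% ± 1.12 (SD, n = 4) in expanded and 42.9% ± 2.15 in single-cell clones, a difference of -23.4 ± 2.31 percentage points, and the exact two-sided sign-flip permutation test gave p = 0.13, the smallest it can give with 4 libraries. The hashtags differ both in their Tcf7 shares and in their numbers of single-cell clones, so this difference mixes hashtags, and Tcf7's own log2 difference was -1.01 in sums per pool and hashtag against -1.61 in sums per library. Without the naive-like and proliferating-like clusters the difference was -6.08 ± 7.90 points with 214 single cells left, the share was higher in expanded clones in pool 1 replicate 1 (by 5.17 points) and lower in the other libraries, and the exact test gave p = 0.25. Among 142 clones of at least 10 cells the Tcf7 share had an SD of 12.3 points, against a median of 11.6 when Tcf7 was permuted over cells within library and hashtag, and the one-sided permutation test gave p = 0.111. For clones of at least 20 cells the permutation p was 0.00107, and for unthinned cells it was 2e-05. Without thinning, detection of Tcf7 also depends on a cell's depth, so the latter p does not separate differences between clones from depth.

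The largest clones of pool 1 used TRBV12-2 with TRBJ2-1 and the CDR3 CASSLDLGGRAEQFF (1274 cells, hashtag 1), TRBV19 with TRBJ1-1 and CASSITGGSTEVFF (704 cells, hashtag 1), and TRBV19 with TRBJ1-1 and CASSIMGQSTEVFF (531 cells, hashtag 3). Tcf7 was detected in 10.2% (8.57 to 12.1), 17.6% (14.7 to 20.7) and 7.82% (5.59 to 10.6) of their thinned cells. Those of pool 2 used TRBV14 with TRBJ1-2 and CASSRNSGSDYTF (997 cells, hashtag 4), TRBV5 with TRBJ2-7 and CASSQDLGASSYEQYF (626 cells, hashtag 1), and TRBV12-2 with TRBJ2-3 and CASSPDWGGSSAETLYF (480 cells, hashtag 2). Their Tcf7 shares were 9.36% (7.57 to 11.4), 30.9% (27.2 to 34.9) and 12.1% (9.21 to 15.5).

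Counted by clone, TRBV19 was the V gene of 11.2% of clones in pool 1 and 10.1% in pool 2, TRBV12-2 of 7.92% and 9.10%, the pair TRBV12-2+TRBV13-2, as the files write it, of 8.37% and 7.52%, TRBV29 of 8.07% and 7.62%, and TRBV12-1 of 6.58% and 7.91%. Fisher's exact test found 0 of 20 V genes different between the pools after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.771, and 0 at an unadjusted p under 0.05. Counted by cell, 16 of 20 passed, but that test takes the cells of a clone as independent, so a few large clones can set its result. TRBV14, for example, made up 0.251% of cells in pool 1 and 12.2% in pool 2, which holds the TRBV14 clone of 997 cells. In a comparison chosen after seeing the data, expanded and single-cell clones differed in 6 of 20 V genes. Naive-like cells made up 82.3% of the single-cell clones and were nearly absent from expanded ones. The test was not run without them, so clone size is not separated here from the contrast of naive-like and other cells. Hashtagged samples hold very different numbers of single-cell clones, and in an exact test stratified by pool and hashtag 5 of the 6 passed. TRBV19 was used by 25.8% (20.05 to 32.3) of expanded and 7.90% (6.52 to 9.46) of single-cell clones, with an adjusted Fisher's exact p of 3.58e-11 (stratified 1.54e-06), and TRBV12-2 by 15.8% (11.1 to 21.5) and 7.08% (5.78 to 8.58), with an adjusted exact p of 0.00113 (stratified 0.0240). TRBV16 (1.44% and 7.75%), TRBV3 (1.44% and 5.54%) and TRBV13-3 (1.91% and 6.27%, with a stratified adjusted p of 0.0995) were less frequent in expanded clones, and TRBV1 was seen in 0 of 209 expanded clones and in 4.06% of single-cell clones.

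The pools were compared last, as the only groups the labels name. The replicates of a pool are repeated loadings of the same 5 hashtagged samples, so these tests measure no spread between samples, and the samples differ widely (stem-like shares of 0.705% to 51.6%). A difference between the pools is therefore not separated from their mix of samples. Gene levels in sums per hashtag were not compared between the pools, because no label says what the hashtags mark. Only the differences by Tcf7 and by clone size were also compared between the pools in such sums, among the flagged results. Pool 2 held more transcript of stem-like, naive-like and exhaustion-associated genes, and pool 1 more of cytotoxic effector genes, by camera with its preset correlation, and none of these lists held with an estimated one. The estimate was -0.0115 (stem-like) and 0.000925 (cytotoxic), below the preset 0.01, and 0.0357 (inhibitory) and 0.105 (naive-like). With few residual degrees of freedom, the lost calls of the stem-like and cytotoxic lists do not show that their genes are correlated. Tox (ENSMUSG00000041272) rose by 0.82 ± 0.05 on the log2 scale (SE, 2 against 2 libraries), from 33.0 ± 1.00 CPM (SD, n = 2) in pool 1 to 56.9 ± 0.921 in pool 2, and Id3 by 0.79 ± 0.08. Klre1 (ENSMUSG00000050241), an NK-type lectin receptor gene, fell by 0.91 ± 0.04, from 110 ± 2.26 to 57.4 ± 1.80 CPM, and Gzma by 0.51 ± 0.03, from 3256 ± 131 to 2227 ± 42.6 CPM. The other large rises were those of the interferon-inducible gene Ifitm1 (0.82 ± 0.11), Fam101b (0.76 ± 0.05), Dapl1 (0.67 ± 0.04), Xcl1 (0.54 ± 0.05), Cd9, Gm20069, Rgs16 and Car2 (0.49 to 0.53). Ifitm1 was uneven among samples. In thinned cells of pool 2 without Tcf7, hashtags 2 and 4 held 386 and 189 of its UMIs, and hashtags 1, 3 and 5 held 3, 0 and 24. In those of pool 1, hashtag 3 held 150 and the others 0 to 33. The other large falls were those of Esm1 (-0.84 ± 0.05), Unc5cl (-0.84 ± 0.08), Fcgr2b (-0.75 ± 0.06), Car5b (-0.54 ± 0.06), Gzmk (-0.52 ± 0.04), and of Ahsa2, Ccr2 and Prdx4 (-0.49 each).

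Of the 18 stem-like genes 10 rose and none fell, or 13 and 0 adjusted over the list alone, with Tcf7 at 0.30 ± 0.04 (127 ± 0.388 to 152 ± 1.99 CPM), Ccr7 at 0.47 ± 0.04 and Slamf6 at 0.34 ± 0.05. Of the 23 cytotoxic genes 16 fell and none rose, or 18 and 0 adjusted over the list alone, with Klrg1 at -0.45 ± 0.04, Zeb2 at -0.41 ± 0.04 and Gzmb at -0.18 ± 0.03. Of 11 naive-like genes 7 rose, or 8 adjusted over the list alone, and of 14 inhibitory genes 8 rose and 1 fell, or 11 and 2 adjusted over the list alone. Cd200 (1.05), Ctla4 (0.39) and Cd160 (0.39) rose, and Havcr2 (-0.51) fell. Ribosomal and translation genes had 7 rises among 16, or 16 adjusted over the list alone, with a median of 0.13. No mitochondrial transcript passed, and 5 of 13 rose adjusted over the list alone. Among 15 proliferation genes Cdca8 (-0.70) fell, and adjusted over the list alone 12 fell and 1 rose. In the interferon list Irf7 (-0.31) fell among 17, also adjusted over the list alone. Immediate early and heat shock genes had 2 rises (Egr1 at 0.25, Junb at 0.13) and 4 falls (Hspa8 at -0.19) among 15, or 4 and 6 adjusted over the list alone.

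Tissue residency genes had 2 rises, Rgs1 and Cd69 (0.16 and 0.14), and 1 fall, Cxcr6 (-0.37), among 8, or 4 and 1 adjusted over the list alone. Slc2a3 (-0.25) fell among 13 glycolysis genes, also adjusted over the list alone. Cd8b1 (-0.22) fell among 9 T cell identity genes, or 3 adjusted over the list alone. Among markers of other cells, Ighm (0.57) rose and Igkc (-0.56) fell of 7 B cell genes, Izumo1r (1.22) rose of 4 CD4 T cell genes, and Fcer1g (2.55) rose of 5 NK genes, from 40 to 276 UMIs. Adjusted over the list alone these were 2 rises and 1 fall, 1 and 1, and 2 rises. Neither of 2 myeloid genes nor Xist (0.07 ± 0.04) passed.

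In all, 479 of 11135 genes passed in edgeR, 223 higher and 256 lower in pool 2. In limma's camera the adjusted p was 8.3e-07 for the stem-like, 3.48e-13 for the cytotoxic, 4.69e-06 for the inhibitory, naive-like and ribosomal, 0.00881 for the mitochondrial, 0.00141 for the proliferation and 0.0444 for the interferon list, and between 0.157 and 0.980 for the others tested. With an estimated correlation none held, at an adjusted p = 0.217 for the stem-like, 0.210 for the cytotoxic, 0.2501 for the inhibitory, 0.266 for the naive-like, 0.785 for the ribosomal, mitochondrial and proliferation lists and 0.807 for the interferon list. The count depended on single libraries: without pool 1 replicate 1 it was 849, without pool 2 replicate 1 it was 140 and without pool 2 replicate 2 it was 169, with 13, 6 and 6 stem-like genes higher and 16, 11 and 13 cytotoxic genes lower, and Klf2 (0.05 ± 0.24 with all libraries) passed at 0.60 without pool 1 replicate 1 and at -0.35 without pool 1 replicate 2. DESeq2 called 175 genes, edgeR without the low-count filter 278, and edgeR on thinned cells 309, and with every cluster left out that the removal rule would strike if read literally, an alternative added after seeing the data, 166 genes passed, with 2 stem-like genes higher and 10 cytotoxic genes lower, and Zeb2 and S1pr5 turned to 0.17 and 0.07.

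The 10 combinations of pool and hashtag are unlabelled samples, and their values are given without comparison. The Tcf7 share had a median of 19.9% over the 10 and ranged from 11.5% to 37.0%. The stem-like share of cells had a median of 19.3% and ranged from 0.705% to 51.6%, the effector-like share had a median of 46.8% (9.90% to 63.3%), and the number of clones had a median of 133.5 (41 to 363).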

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

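Tests chosen only after the result was seen were those of naive-like cells, of fewer cells and of TRB sequence errors in the clone comparison, of hashtag mixes in the pool differences, of naive-like cells, hashtag shares and cytotoxic genes in the ribosomal pattern, and of other splits of the sums, and the bounds that decide them were set with results known.

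The difference between cells with and without Tcf7 itself differed between the pools for 24 of 9538 genes in edgeR, as a test of the interaction of class and pool, and 10 of these were TCR segments. Ifitm1, an interferon-inducible gene, was 1.46 higher with Tcf7 in pool 1 and 0.62 lower in pool 2 on the log2 scale, a difference of -2.08. In sums per hashtag Ifitm1 was 2.00 ± 0.19 (SE) higher with Tcf7 in pool 1 and 0.23 ± 0.22 higher in pool 2, where hashtag 2 stood at 0.44 (386 UMIs without and 68 with Tcf7) and hashtag 4 at 0.28 (189 and 36), whereas hashtag 5 had 24 UMIs without and none with Tcf7 and hashtag 1 had 3 and none. The falls were deeper in pool 2 for the cytotoxic and effector genes Gzma (difference -0.37), Ccl5 (-0.16), Gzmb (-0.44), S1pr5 (-0.53), Lgals1 (-0.18), Id2 (-0.21) and Cx3cr1 (-0.45), and for Ahnak (-0.26), Klrc1 (-0.24), Lgals3 (-0.28), Cd7 (-0.28) and Crip1 (-0.14), while Gm42418 differed by 0.14.

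In the same test by clone size 6 of 9270 genes differed between the pools. The rise of Gzma in expanded clones was 3.05 in pool 1 and 4.30 in pool 2, a difference of 1.25, and Ccl5 differed by 0.37. Ccr7 (0.63), Cd6 (0.95), Rgs16 (2.26) and Fam101b (0.87) were the others. In sums per hashtag Gzma alone of the 6 passed, at 0.996 with an adjusted p of 0.00381 in edgeR. That fit takes the unlabelled hashtags of a pool as its replicates. Ccr7 turned to -0.15 and Fam101b fell to 0.31, and these 2, Cd6 (0.65) and Ccl5 (0.43) had an adjusted p of 0.998 and Rgs16 (1.65) one of 0.425.

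The TCR libraries also held contigs of chains that no comparison used. There were 47 contigs of IGH, 13 of IGK and 5 of TRD among 56784, none of them productive, and the libraries listed 2978 contigs of more than 1 chain type, 22 of them productive, and 160 without a chain. No biological or technical explanation was tested for these.

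Far fewer genes differed by clone size once naive-like and proliferating-like cells were left out, 279 in place of 2921. The data argue against fewer cells as the whole cause, as 10 random draws of 214 single cells gave between 816 and 934 genes. Fewer cells still took the count from 2921 to a median of 889 in these draws, so part of the lost calls goes with cell number. The data also argue against sequencing errors of 1 base in TRB as the whole cause. Of the 214 single-cell clones left, 9.35% (5.80 to 14.1) lay 1 base from an expanded clone of the same hashtag, and without them too 306 genes passed and a median share of 0.453 of the log2 difference was kept. A candidate explanation is the naive-like cells among single-cell clones. Genes called with all cells kept a median share of 0.421 of their log2 difference without the naive-like and proliferating-like clusters, and 2323 of 2803 kept their direction. The 2 clusters were left out together, and they held 82.3% and 0.738% of the cells of single-cell clones. Clusters were built from the same expression values, so part of this loss follows by construction. The 8 sums are paired by library, and the 8 splits that part every pair are too few for a share under 0.05: the real 1 gave 2921 genes and the highest of the others 0.

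The cytotoxic genes that changed with Tcf7 by different amounts in the pools may reflect different mixes of hashtags. In sums per hashtag the difference of Ifitm1 was -1.76, with an adjusted p of 0.0123 in edgeR. These sums remove mixing of hashtags within the classes. They cannot exclude a different mix of samples, because each pool keeps its own unlabelled hashtags, which served as replicates. Within pool 1, hashtags 3 and 5 stood at 2.01 and 2.29, hashtags 1 and 2 at 0.62 and 1.45, and hashtag 4 had no UMI without Tcf7. Most hashtags held few Ifitm1 UMIs. The fall of Ifitm1 in pool 2 cannot be told apart from a different mix of hashtags in cells with and without Tcf7, since in sums per hashtag it stood at 0.23 ± 0.22, with hashtags 2 and 4 higher and hashtags 1 and 5 lower on few UMIs. The bound of this test was made stricter after its result was seen. For the other 13 genes outside the TCR segments a median share of 0.828 (0.487 to 1.09) of the difference was left in sums per hashtag, all 13 in the same direction, 5 at an unadjusted p under 0.05 and 0 after adjustment, so hashtag mixes cannot be told apart from a difference between the pools with this number of hashtags. By hashtag, the log2 CPM difference of Gzma with Tcf7 was -0.97, -2.51, -1.03, -2.53 and -1.75 for hashtags 1 to 5 of pool 1. For those of pool 2 it was -2.07, -1.22, -3.08, -1.01 and -2.61. The values of the 2 pools overlapped, and they varied more within each pool than the pool difference of -0.37. What distinguishes the pools is not stated, and no biological explanation was tested.

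Ribosomal protein and mitochondrially encoded transcripts were higher in cells with Tcf7. The data argue against naive-like cells as the whole source, as 16 of 16 ribosomal genes rose without the naive-like and proliferating-like clusters, with a median of 0.37 in place of 0.44, and against different Tcf7 shares of the hashtags as the whole source, as 16 of 16 rose in sums per hashtag. The median there was 0.25 and 11 of 13 mitochondrial transcripts rose, so part of the size may go with the hashtags. The fall of abundant cytotoxic genes shifts all other genes by at most 0.0330 (log2) in a library, below the list's median of 0.25 in sums per hashtag. Of the 8 splits that part every library's sums, again too few for a share under 0.05, the real 1 gave 1663 genes for Tcf7 and the highest of the others 0. Whether cells with Tcf7 hold more translation-related transcript stays open, since the depth-matched cells may still differ in total RNA.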

How the results depend on the processing

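Tests chosen after seeing the data were those that leave out the naive-like and proliferating-like clusters, the low-UMI cluster, or the clusters struck by the literal removal rule, the pool difference in Tcf7 share without each library, and the test of TRBV use by clone size stratified by pool and hashtag, in which 5 genes passed in place of 6. Values are log2 differences unless named otherwise. Where a value moved, the cause was not tested, except that by construction fewer cells enter in the thinned and cluster-free settings, fewer genes are tested in sums per hashtag, and more are tested without the low-count filter.

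The count of genes that differed between the pools (479) was 175 with DESeq2, 278 without the low-count filter, 309 with thinned cells, 166 with the literal removal rule and 1081 with replicate number as a block, and 140 to 849 when 1 library was left out. The labels do not say that replicate numbers pair libraries across the pools. The correlation of replicate 1's deviation between the 2 pools was 0.103, which leaves open whether they do. It was 428 to 490 with DESeq2 size factors, the lower cell filter, only cells with a TCR contig, hashtag multiplets kept, or without the low-UMI cluster. Where a library was left out, the single library of that pool was assumed to vary like the others.

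With Tcf7, the count (1663) was 711 with DESeq2, 1101 without the library block, 858 with the literal removal rule, 590 in sums per pool and hashtag, 3882 with unthinned cells and 3852 with at least 2 Tcf7 UMIs, and 1249 to 1470 when 1 library was left out. By clone size, the count (2921) was 1722 in sums per pool and hashtag and 279 without the naive-like and proliferating-like clusters, and 2383 to 2619 when 1 library was left out. Restricting the clone comparison to cells with a productive TCR contig keeps the same cells by construction and was not run.

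With an estimated correlation, camera's adjusted p between the pools was 0.217 (stem-like), 0.210 (cytotoxic), 0.2501 (inhibitory), 0.266 (naive-like), 0.785 (proliferation, mitochondrial and ribosomal) and 0.807 (interferon). With Tcf7 it was 0.175 (cytotoxic), 0.124 (inhibitory), 0.282 (proliferation), 0.105 (mitochondrial), 0.114 (ribosomal) and 0.397 (NK). By clone size it was 0.164 (stem-like, cytotoxic and naive-like), 0.238 (inhibitory and mitochondrial) and 0.2496 (ribosomal).

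Between the pools, 24 of 1495 pairs of named gene and setting turned direction, 137 lost and 46 gained a call. The literal removal rule turned Ccl4 to 0.039, Cd3d to -0.0091, Cd69 to -0.021, Cxcr3 to -0.052, S1pr1 to 0.025, S1pr5 to 0.072 and Zeb2 to 0.17. Thinning turned Eomes to 0.054, Ifng to 0.0041 and S100a6 to 0.029. The lower cell filter turned H2-Aa to 0.11, keeping multiplets turned Ifng to 0.0030, and only cells with a TCR contig turned Tyrobp to -0.057. With 1 library left out the ranges were Bach2 -0.031 to 0.49, Cd68 -0.32 to 0.12, Eomes -0.22 to 0.17, H2-Aa -0.66 to 0.092, Klf2 -0.35 to 0.60 and S100a6 -0.040 to 0.027. For Ifng, pool 2 against pool 1, the range was -0.026 to 0.013.

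With Tcf7, 11 of 1583 pairs turned direction, 60 lost and 19 gained a call. At least 2 Tcf7 UMIs turned 2810417H13Rik to 0.53, Cd68 to -0.10 and S1pr1 to 0.044, and unthinned cells turned S1pr1 to 0.018. The literal removal rule turned Bst2 to -0.023 and Cd40lg to -0.063, and leaving out naive-like and proliferating-like cells turned Ifng to 0.087 and Satb1 to -0.12. With 1 library left out the ranges were Cd40lg -0.0039 to 0.44, Cd68 -0.15 to 0.31 and S1pr1 -0.066 to 0.014.

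By clone size, 28 of 1681 pairs turned direction, 76 lost and 1 gained a call. Leaving out naive-like and proliferating-like cells turned Cd40lg to -1.06, Il7r to -0.045, Klf2 to 0.30, Klra9 to -0.48, Rgs1 to -0.041, S1pr1 to 0.57 and Tyrobp to -0.68. Sums per pool and hashtag turned Eomes to 0.26, Slamf6 to 0.15 and Xcl1 to 0.97. The literal removal rule turned Eomes to 0.13 and Xcl1 to 0.64, leaving out each pool's largest clone turned them to 0.074 and 0.20, and no low-count filter to 0.024 and 0.039. Identical TRB and TRA turned Cd40lg to -0.34 and Xcl1 to 0.0088, and Cd74 turned to -0.019 with the lower cell filter and to -0.73 with unthinned cells. With 1 library left out the ranges were Cd40lg -0.10 to 0.11, Cd74 -0.12 to 0.58, Eomes -0.17 to 0.081, Tyrobp -0.053 to 0.22 and Xcl1 -0.16 to 0.058.

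The Tcf7 share of pool 1 replicates 1 and 2 and pool 2 replicates 1 and 2 was 28.8%, 27.1%, 32.7% and 33.4% with unthinned cells and 18.6%, 17.9%, 20.2% and 20.05% without the naive-like cluster. The pool difference stayed between 2.17 and 2.79 points when 1 library was left out. The difference between expanded and single-cell clones stayed negative, between -24.3 and -22.4 points when 1 library was left out. The permutation p of the spread between clones was 0.00107 for clones of at least 20 cells and 2.0e-05 with unthinned cells, against 0.101 to 0.111 in the others. By CDR3 amino acids, libraries of different pools shared 6.18%, 6.18%, 5.80% and 5.54% of clones. Counted by cells, 16 TRBV genes passed between the pools, in a test that takes the cells of a clone as independent, and counted by clones 0 passed. At Leiden resolution 1.0 the mean effector-like share was 49.5% in pool 1 and 41.0% in pool 2 and the stem-like share 12.4% and 19.4%. At 0.4 the effector-like share of pool 2 was 38.5% and the stem-like share 0 in both. Depth limits Tcf7 detection per cell, as the unthinned shares show.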

Other observations

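No explanation was tested here, and the values per hashtag and the receptor sharing were looked at after the results were seen, with no tests of their own.

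Receptors recurred across hashtagged samples. Of 175 expanded clones by TRB amino acid sequence, 20 were found under at least 2 combinations of pool and hashtag and 13 in both pools. TRBV12-2 with TRBJ2-3 and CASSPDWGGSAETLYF was found under 5 of them, in 136 cells and 4 nucleotide sequences. TRBV19 with TRBJ1-1 and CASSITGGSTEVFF was found under 4, in 1095 cells and 3 nucleotide sequences, and TRBV19 with TRBJ1-6 and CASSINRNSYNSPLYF under 4, in 482 cells and 2 nucleotide sequences.

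Some values per hashtag left wide gaps: no stem-like share lay between 2.81% and 35.7% and no Tcf7 share between 14.3% and 25.5%, whereas the effector-like shares had a value of 38.9% between the lower and the higher ones. That value, of pool 2 hashtag 3, joined 6.26% of cells in the larger effector-like cluster and 32.7% in the smaller one. For the larger effector-like cluster alone, no share lay between 9.37% and 53.1%. For hashtags 1 to 5 of pool 1 the stem-like share of cells was 2.23%, 44.0%, 1.45%, 51.6% and 2.69%, and for those of pool 2 it was 49.5%, 0.705%, 40.6%, 2.81% and 35.7%. The effector-like share was 63.3%, 9.90%, 62.8%, 22.1% and 57.9%, and 15.2%, 60.1%, 38.9%, 54.7% and 21.9%. The naive-like share was 0.709%, 15.7%, 0.371%, 14.1% and 0.641%, and 14.5%, 0.415%, 8.28%, 0.396% and 14.6%. Tcf7 was detected in 14.0%, 32.02%, 12.6%, 37.0% and 14.3% of thinned cells, and in 34.7%, 11.5%, 25.5%, 13.6% and 28.6%. The number of clones was 59, 288, 51, 225 and 46, and 343, 41, 208, 56 and 363. No label says what the hashtags mark, so these samples were not grouped.

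Klf2, a transcription factor gene linked to T cell quiescence and migration, differed between the replicates of each pool, at 1659 and 876 CPM in pool 1 and 1538 and 1037 CPM in pool 2. The hemoglobin gene Hbb-bs stood at 82.8 CPM in kept cells of pool 2 replicate 1 and at 0.109 to 0.196 CPM in the other libraries.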
